A study of Xenopus laevis with 4 samples.

How the data were processed

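The data are 4 RNA-seq libraries from Xenopus laevis embryos collected at the mid-blastula transition, about 9 hours after fertilization per the labels. The mid-blastula transition is the stage at which the embryo begins large-scale transcription of its own genome. Per the labels' protocols, embryos for the captured libraries were injected at the 1-cell stage with 10 nl of 50 mM 5-ethynyl uridine (EU), a uridine analogue that is built into RNA made after the injection. The EU-containing RNA was linked to biotin by click chemistry and pulled down on streptavidin beads. The 2 EU-RNA libraries were made from this captured RNA. The 2 libraries of the Normal group were made from total RNA of embryos that were not injected, and the labels describe that RNA as maternal and newly made RNA together. The 2 groups therefore differ in the capture step and also in the injection. Both kinds of library were prepared with a kit designed for RNA from fixed human tissue, per the labels' protocols.

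The authors deposited a single table of estimated counts per gene, in whole numbers, with a column for each library and no pooling. Per the submitters' processing notes, bcl2fastq and Salmon 0.12.0 were used. Salmon assigns reads to transcripts by pseudo-alignment and splits reads that fit several transcripts between them. The file's name refers to tximport, a tool that sums transcript estimates to genes. Whether the estimated counts were scaled by transcript length, which transcript set was indexed and how the deposited values were rounded is not given in the sources used here. The genome build is also not given in the sources used here, so no coordinates are printed. No column of per-sample values was left unused. Features carry gene symbols with .L or .S for the long and short chromosome of each homeologous pair, or an identifier without a symbol. X. laevis is allotetraploid, so many genes exist as near-identical L and S copies, and reads shared between homeologs or tandem copies can be split wrongly between them. Values of a single copy of such a gene are uncertain in that respect. Whether counting used the strand of the reads is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

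Column totals were 81201990 and 117849586 estimated counts for EU-RNA replicates 1 and 2, and 47598265 and 209445802 for Normal replicates 1 and 2. A feature with 0 counts in a library may be present at up to 3 counts of that total, which is 0.0369 and 0.0255 CPM (counts scaled to a common library total) for the EU-RNA libraries and 0.0630 and 0.0143 CPM for the Normal libraries. Such floors cover counting error only. The labels do not say that replicates came from separate clutches or cultures, so p-values measure the spread between these libraries, which may be technical.

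The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on the estimated counts, rounded to whole numbers, with TMM factors, the default filterByExpr filter, group as the only term and Benjamini-Hochberg adjustment over all features tested, with a threshold of 0.05. Of 49078 features in the table, 26543 passed the filter. Log2 fold changes are EU-RNA over Normal, and each standard error (SE) is the size of the log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, as mean ± SD over 2 libraries. TMM sets the average transcript of the table to about 0, so a fold change is a position relative to the average transcript and not an absolute amount. For a feature with 0 counts in both libraries of a group, the fold is a lower bound computed with a floor of 3 counts over that group.

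Before the data were examined, 16 gene lists were fixed, together with the tests, the alternatives and the rule for naming genes. List members were matched to symbols without the .L or .S ending. The pattern for mitochondrially encoded genes matched only 2 features, the homeologs of trnt1, a nuclear gene, so that list was not tested and the other 15 were. Each list was tested with camera in edgeR, which compares the list with all other genes, at a preset inter-gene correlation of 0.01 and with adjustment over the 15 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. Named genes are the 10 symbols with the largest and the 10 with the smallest log2 fold change among called features with an average log2 CPM of at least 3 and no overlap between the groups, the 4 members of each list with the smallest p, and the 3 most abundant features of each group. A gene that this rule names in the ribosomal protein list is not reported here. Identifiers without a symbol were passed over, 26 among the higher and 48 among the lower features. Other genes named below were chosen after their values were seen, most of them as members of a list or a name family. Some, such as nfatc1.S and znf33a.L, were named for their own values or position.

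The fit was tested on simulated data drawn from the real means, library sizes and dispersions of the EU-RNA against Normal comparison over 26543 features. The changed features all had a mean of at least 8 CPM. Each feature had the same dispersion in both groups, although replicate log2 ratios had an SD of 0.90 in EU-RNA and 0.46 in total RNA. The recovery given here applies to features of that abundance and to equal spread. With 200 features changed 4-fold, 103 were recovered among 114 calls, and with 200 features changed 16-fold, 168 were recovered among 194 calls. No recovered feature had the wrong direction. The false calls numbered 11 and 26, a larger share than the threshold of 0.05 promises.

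Alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma-voom in limma 3.58.1, the replicate number as a block, each library left out, the 10 most abundant features left out and homeologs summed. Thinning all libraries to the smallest total was added after seeing the data. Homeolog pairs were compared with an exact McNemar test. A RefSeq gene table of assembly Xenopus_laevis_v10.1, of which 26215 of the 49078 feature names matched a symbol, was used for names, gene classes and gene order only.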

Results

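RNA was measured in 2 libraries of EU-labelled, captured RNA and 2 libraries of total RNA from X. laevis embryos at the mid-blastula transition. The totals were 81201990 and 117849586 estimated counts for the EU-RNA libraries and 47598265 and 209445802 for the total RNA libraries. Counts above 0 were present for 24478 and 25888 features in the EU-RNA libraries and for 25092 and 32448 in the total RNA (Normal) libraries. A single feature, LOC108705792, a locus without a gene symbol, held 28.6% ± 0.744 (SD, n = 2) of all counts in total RNA and 0.0220% ± 0.000663 (SD, n = 2) in EU-RNA. The most abundant feature of EU-RNA was ccdc50.L, at 4.54% ± 0.393 of counts against 7.67% ± 0.448 in total RNA (SD, n = 2). It was followed in EU-RNA by the symbol-less features Xelaev18003734m, at 0.893% ± 0.189 of counts, and LOC108705162, at 0.853% ± 0.620 (SD, n = 2). The EU-RNA excess of these 2 features did not pass the edgeR test (log2 fold changes of 1.36 and 2.46, adjusted p = 0.0821 and 0.0736). It did by DESeq2, without a filter and with scaling by library size only. The log2 fold change of LOC108705162 was 1.27 without EU-RNA replicate 1 and 3.03 without EU-RNA replicate 2. In total RNA the third most abundant feature was the histone gene hist1h2bj.S, at 0.821% ± 0.0657 of counts against 0.645% ± 0.0582 in EU-RNA (SD, n = 2). Across all features, log2(CPM + 1) correlated with Pearson's r of 0.979 between the total RNA libraries and 0.929 between the EU-RNA libraries. It was 0.879 to 0.926 between libraries of different groups. These values include 14000 features with 0 counts in all libraries. Over tested features only, r was 0.967 between the total RNA libraries and 0.882 between the EU-RNA libraries. Between libraries of different groups it was then 0.792 to 0.870. Over 12933 features with an average log2 CPM of at least 3, the log2 ratio between replicates had an SD of 0.90 in EU-RNA and 0.46 in total RNA.

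The comparison of the captured fraction with total RNA asks which transcripts were made after the start of development, against a background that also holds maternal RNA. Of 26543 features tested, 1246 were higher and 236 were lower in EU-RNA by edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p below 0.05, and 25061 did not pass. Of the higher features, 398 differed by at least 8-fold, as did 110 of the lower ones. Features without a gene symbol made up 464 of the higher and 107 of the lower calls.

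Among called features with a symbol and an average log2 CPM of at least 3, the 10 with the largest differences in favour of EU-RNA were mostly at very low levels in total RNA. cnga1.L, which encodes a subunit of the photoreceptor cyclic nucleotide-gated channel, was at 40.5 ± 2.74 CPM in EU-RNA and had 0 and 4 counts in the total RNA libraries, a log2 fold change of 11.19 (SE 0.73, edgeR adjusted p = 0.00358). The cell adhesion gene bcam.L (10.08, SE 0.99) and the nuclear receptor gene hnf4b.L (9.58, SE 1.55) followed. fcn1.L, which encodes a ficolin, a secreted lectin, was the most abundant of the 10, with 289 ± 131 CPM against 3.86 ± 1.60 CPM (SD, n = 2). The remaining 6 were sncaip.L (8.30), fcn2-A (7.85), alox5ap.L (7.39), clec3b.S (7.28), the ammonium transporter gene rhcg.L (7.18) and ca8.L (6.08, log2 fold changes). By limma-voom, 8 of these 10 no longer passed (limma adjusted p from 0.0610 for hnf4b.L to 0.137 for rhcg.L), while cnga1.L and fcn1.L did. Total RNA also holds newly made RNA, per the labels, and came from embryos that were not injected. The size of these ratios therefore does not rank genes by new transcription.

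At the other end, among called features with a symbol under the same minimum of abundance, dsg4.L, a desmosomal cadherin gene, had 0 counts in both EU-RNA libraries and 50.5 ± 1.07 CPM in total RNA (SD, n = 2), which places it at least 3656-fold lower in EU-RNA. ank3.S, which encodes an ankyrin, also had 0 counts in EU-RNA and was at least 2695-fold lower. Bounds of this kind cover counting error only. With all libraries thinned to the smallest total, 1938 features had at least 100 counts in one EU-RNA library and 0 in the other. Between the total RNA libraries there were 120. A count of 0 in EU-RNA therefore need not mean absence. Before thinning, features split in this way between the EU-RNA libraries were mostly rare in total RNA. They made up 18.5% of the lowest tercile of tested features by total RNA abundance and 0.102% of the highest. The sarcomere gene nexn.L (-9.56, SE 0.72), dok1.S (-8.97, SE 1.29) and the DNA repair gene parp2.L (-7.88, SE 0.76) were lower on the log2 scale, as were the homeobox gene zfhx4.L (-4.75, SE 0.29) and bcar3.S (-3.25, SE 0.45). glt8d1.L (-2.83), sh3bgrl2.L (-2.66) and tor1b.L (-2.42) completed the 10 above that minimum. Some rarer genes differed by more than these 3, such as nfatc1.S, which had 0 counts in both EU-RNA libraries and was at least 979-fold lower (edgeR adjusted p = 0.0151). LOC108705792 had a log2 fold change of -10.60 (SE 0.75, edgeR adjusted p = 0.00358), whereas ccdc50.L (-1.02, edgeR adjusted p = 0.197) and hist1h2bj.S (-0.60, edgeR adjusted p = 0.260) did not pass. Both did by DESeq2 (adjusted p = 5.47e-15 and 0.00409) and by limma-voom (adjusted p = 2.90e-05 and 0.0105), and ccdc50.L also with a stricter filter (edgeR adjusted p = 0.0116). Their log2 fold changes were -1.04 and -0.82 without EU-RNA replicate 1, and -1.10 and -0.50 without EU-RNA replicate 2. The calls of glt8d1.L, sh3bgrl2.L and tor1b.L were lost without Normal replicate 1, with edgeR adjusted p of 0.369, 0.0592 and 0.246, and those of glt8d1.L and sh3bgrl2.L also without Normal replicate 2, with 0.106 and 0.0949. By limma-voom nexn.L did not pass (limma adjusted p = 0.0504). The total count of lower features was 151 without Normal replicate 1, of which 105 were among the 236.

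With an EU-RNA library left out, edgeR called more features in both directions. The lone EU-RNA library is then assumed to vary like the total RNA libraries. Calls of such fits, here and below, therefore hold no spread between EU-RNA libraries. The filter also passed more features, 31540 without EU-RNA replicate 1 and 30657 without EU-RNA replicate 2. The shares of these 2 changes in the rise were not separated. All of the 1246 higher and 236 lower features of the full fit were among the calls of both of these fits.

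Genes of the early embryonic patterning programme were higher in EU-RNA across the dorsal, endodermal and mesodermal lists. By edgeR, of 26 tested genes of the organizer and dorsal list, 14 were higher and none lower, with a median log2 fold change of 2.67. Adjusted over the list alone, 22 were higher. The Nodal-related ligand gene nodal3.2.L stood at 116 ± 4.54 CPM in EU-RNA and 6.56 ± 0.458 CPM in total RNA (SD, n = 2), a log2 fold change of 4.14 (SE 0.23, edgeR adjusted p = 0.00358). The tandem gene nodal3.1.L, which may share reads with it (3.78, SE 0.26), and both homeologs of the forkhead gene foxa4 (3.25, SE 0.25 for foxa4.L and 2.69, SE 0.20 for foxa4.S) were also higher, as were chrd.1.S, which encodes the BMP antagonist chordin (2.86, SE 0.24), and the homeobox gene gsc.S (3.39, SE 0.43). The list stood above other genes by camera (adjusted p = 1.82e-25). It had an adjusted p = 0.0900 with an estimated correlation. Without EU-RNA replicate 2, 23 genes of the list were higher.

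In the list of Nodal ligands and endoderm genes, 20 of 33 tested genes were higher and none lower, with a median log2 fold change of 2.18, and 22 were higher adjusted over the list alone. The homeobox genes bix1.1.L (2.79, SE 0.20) and bix1.2.S (2.84, SE 0.21), the Nodal inhibitor gene lefty.L (3.28, SE 0.23) and the endoderm transcription factor gene sox17b.2.L (2.62, SE 0.20) had the smallest p. bix1.1.L reached 658 ± 1.27 CPM in EU-RNA against 94.9 ± 9.06 CPM in total RNA (SD, n = 2). Of the early Nodal genes, nodal5.L was higher by 4.94 (SE 0.75) and nodal6.L by 3.92 (SE 0.42) on the log2 scale. The list's camera adjusted p was 7.32e-25, and 0.0498 with an estimated correlation.

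Of 56 tested mesoderm and ventrolateral genes, 25 were higher and none lower, with a median log2 fold change of 2.103. Adjusted over the list alone, 33 were higher and 1 lower. The apelin receptor gene aplnr.S was at 183 ± 20.3 CPM in EU-RNA and 7.01 ± 0.713 CPM in total RNA (SD, n = 2), a log2 fold change of 4.70 (SE 0.24, edgeR adjusted p = 0.00358). The T-box gene eomes.L (2.84, SE 0.19), the BMP target homeobox gene ventx3.2.L (2.72, SE 0.21) and the BMP pseudoreceptor gene bambi.L (2.37, SE 0.19) were next. tbxt.S, which encodes Brachyury (1.93, SE 0.24), and wnt8a.L (2.54, SE 0.25) were higher too. The list's camera adjusted p was 3.16e-26, and 0.0498 with an estimated correlation.

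**Figure D1:**
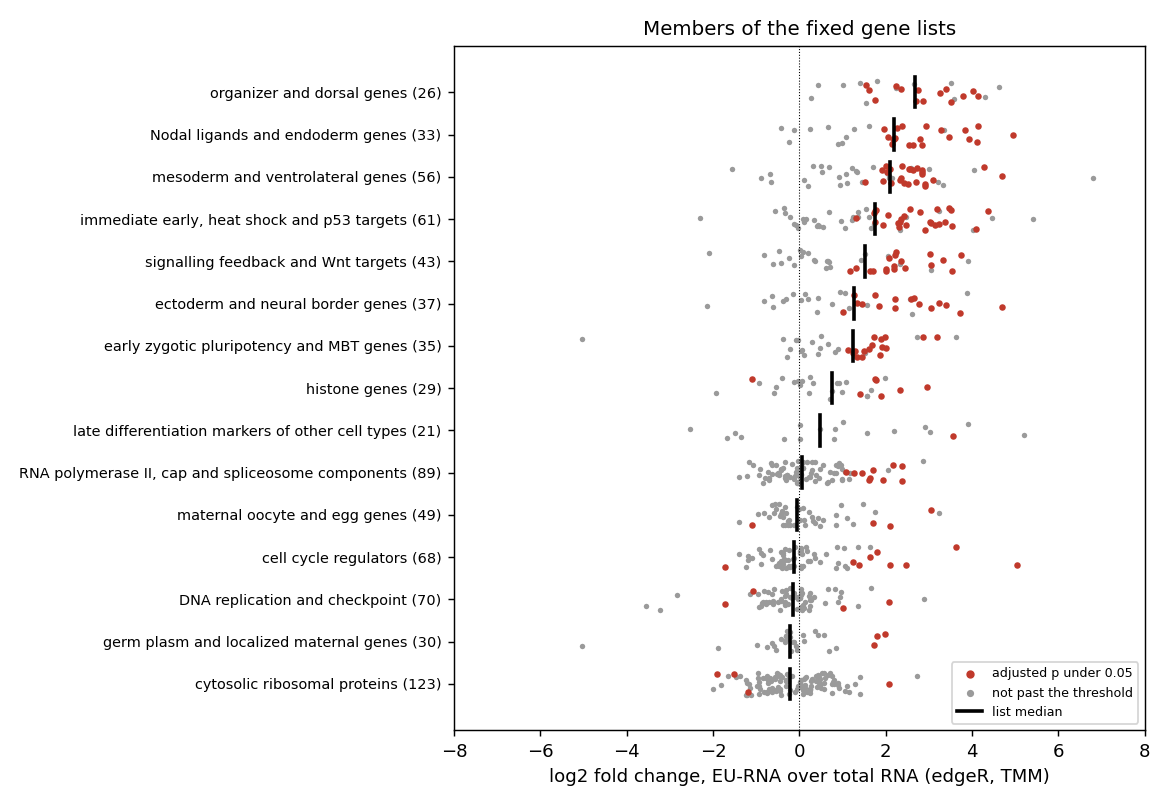
Each point is a tested member of a gene list, placed by its log2 fold change of EU-RNA over total RNA (2 libraries each), in red where the edgeR adjusted p was below 0.05. Black bars are list medians over all tested members and the number tested is in brackets; 1 point beyond 8 on the axis and 11 points for genes with 0 counts in a whole group are not drawn. Medians run from 2.67 for organizer and dorsal genes to -0.22 for ribosomal proteins.

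Ectodermal genes were also higher, with 16 of 37 tested members of the ectoderm and neural border list higher, none lower and a median log2 fold change of 1.25. Adjusted over the list alone, 18 were higher and 2 lower. The epidermal regulator gene grhl3.S was at 549 ± 88.6 CPM in EU-RNA and 41.5 ± 9.45 CPM in total RNA (SD, n = 2), a log2 fold change of 3.73 (SE 0.27, edgeR adjusted p = 0.00358). The forkhead genes foxi1.L (4.68, SE 0.34), foxi4.2.S (2.21, SE 0.19) and foxi4.2.L (2.22, SE 0.20) passed with it. The list's camera adjusted p was 2.97e-11, and 0.0498 with an estimated correlation.

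Of 35 tested genes of the early zygotic pluripotency list, 16 were higher and none lower, with a median log2 fold change of 1.24, and 20 were higher adjusted over the list alone. gs17.S, a gene named for its expression at gastrulation, was at 354 ± 23.8 CPM against 39.2 ± 1.17 CPM (SD, n = 2), a log2 fold change of 3.18 (SE 0.20). The anti-apoptotic gene mcl1.S (2.86, SE 0.21), tmcc1.S (1.97, SE 0.20) and klf2.L (1.86, SE 0.22) followed. pou5f3.2.L, a homologue of the pluripotency factor gene Oct4, was among the most abundant members, at 2673 ± 22.5 CPM in EU-RNA and 1068 ± 87.5 CPM in total RNA (SD, n = 2), a log2 fold change of 1.32 (SE 0.22, edgeR adjusted p = 0.0253). The list's camera adjusted p was 6.40e-13, and 0.0498 with an estimated correlation.

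Feedback and target genes of signalling pathways were higher in 18 of 43 tested members, with none lower and a median log2 fold change of 1.51. Adjusted over the list alone, 21 were higher. Both homeologs of the FGF feedback inhibitor gene spry2 (3.34, SE 0.23 for spry2.L and 3.74, SE 0.29 for spry2.S), the Wnt target sp5l.L (2.35, SE 0.19) and spry1.L (2.46, SE 0.20) had the smallest p, and the Wnt feedback gene axin2.L was higher by 2.22 (SE 0.20). The list's camera adjusted p was 5.01e-15, while adjusted p = 0.0900 with an estimated correlation.

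The list of immediate early, heat shock and p53 target genes was also higher, with 27 of 61 tested genes higher, none lower and a median log2 fold change of 1.75. Adjusted over the list alone, 33 were higher. The MAP kinase phosphatase gene dusp1.S was at 521 ± 55.6 CPM in EU-RNA and 25.2 ± 2.52 CPM in total RNA (SD, n = 2), a log2 fold change of 4.37 (SE 0.22, edgeR adjusted p = 0.00358). The p53 targets ccng1.L (3.52, SE 0.22), gadd45a.L (3.22, SE 0.23) and mdm2.L (3.46, SE 0.25) were next. In a split by class that was not fixed beforehand, 12 of 15 features of p53 and its targets were higher with a median of 2.80, 14 of 37 immediate early and other genes with a median of 1.74, and 1 of 9 heat shock genes with a median of 0.34 (log2 scale). The heat shock member that passed was hspa1l.S (1.31, SE 0.20). Only the EU-RNA libraries came from injected embryos. The list's camera adjusted p was 5.91e-23, and 0.0498 with an estimated correlation.

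In these 7 lists, in which edgeR called no gene lower, genes with a negative fold change and an unadjusted p below 0.05 numbered 0 for the organizer, early zygotic and signalling lists, 2 for the Nodal and endoderm list, 1 for the mesoderm list, 3 for the ectoderm list and 1 for the immediate early list. DESeq2 called 1 mesoderm, 3 ectoderm and 1 early zygotic gene lower and none in the other 4 lists, and limma-voom called none lower in any of the 7. Without EU-RNA replicate 1, edgeR called 2 ectoderm, 2 mesoderm and 2 immediate early list genes and 1 gene each of the Nodal, early zygotic and signalling lists lower, and without EU-RNA replicate 2 it called 4 ectoderm, 3 early zygotic, 1 mesoderm and 1 immediate early list gene lower.

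**Figure D2:**
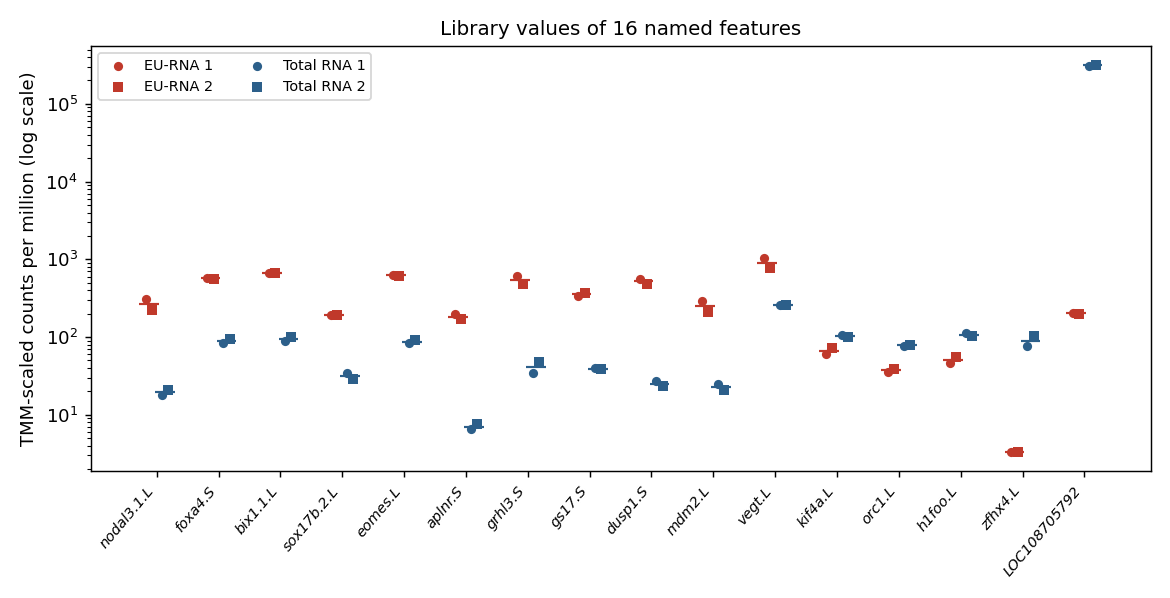
TMM-scaled CPM on a log axis for 16 named features, with a point for each of the 2 EU-RNA (red) and 2 total RNA (blue) libraries and a line at each group's mean. In 11 features both EU-RNA libraries lie above both total RNA libraries, as for vegt.L, and in the other 5, kif4a.L, orc1.L, h1foo.L, zfhx4.L and LOC108705792, both lie below.

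The ratio of EU-RNA to total RNA of maternal genes was mostly near that of the average transcript. In the germ plasm and localized maternal list, 3 of 30 tested genes were higher, none lower and 27 did not pass, with the same counts adjusted over the list alone. The 3 were wnt11b.L (1.99, SE 0.21), a Wnt ligand gene of the vegetal cortex, and both homeologs of the vegetal T-box gene vegt (1.81, SE 0.23 for vegt.L and 1.72, SE 0.22 for vegt.S). vegt.L reached 901 ± 190 CPM against 257 ± 0.574 CPM (SD, n = 2). kif4a.L, with a log2 fold change of -0.64 (SE 0.20, edgeR adjusted p = 0.144), did not pass. Its log2 fold change was -0.57 without EU-RNA replicate 1 and -0.83 without EU-RNA replicate 2. The list's median of -0.21 and mean of -0.16 lay below 0 while camera's direction was upward, with an adjusted p of 0.852. With scaling by library size only the list's median was 0.051. Against the 0 lower genes of edgeR, 2 had an unadjusted p below 0.05, DESeq2 called 1 and limma-voom 0, and 4 and 8 were called without EU-RNA replicate 1 and 2.

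In the maternal oocyte and egg list, 3 of 49 tested genes were higher and 1 was lower, again with the same counts adjusted over the list alone. fbxo5.L, which encodes an inhibitor of the anaphase-promoting complex (3.05, SE 0.33), the ubiquitin ligase gene rnf114.L (1.71, SE 0.24) and the RNA-binding protein gene lin28a.S (2.097, SE 0.31) were higher. The oocyte-type linker histone gene h1foo.L was at 50.5 ± 6.83 CPM against 107 ± 8.21 CPM (SD, n = 2), a log2 fold change of -1.09 (SE 0.21, edgeR adjusted p = 0.0414), a call lost without Normal replicate 1 (adjusted p = 0.216), without Normal replicate 2 (adjusted p = 0.0662) and with scaling by library size only (adjusted p = 0.107). The median of -0.06 and the mean of 0.42 differed in sign, and camera gave an upward direction with an adjusted p of 0.639. Scaling by library size only moved this median to 0.17, and leaving out Normal replicate 2 moved it to 0.12. Without EU-RNA replicate 1, 11 of its genes were higher and 9 lower, and without EU-RNA replicate 2, 9 and 5.

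Most cell cycle, replication and ribosomal protein genes did not pass either. Of 68 tested cell cycle regulators, 8 were higher and 1 was lower, and adjusted over the list alone 10 were higher and 6 lower. The largest of the 4 with the smallest p was cdkn1a.L, which encodes the CDK inhibitor p21 (3.62, SE 0.26), followed by the CDK gene cdk2.S (2.46, SE 0.34), the cyclin E gene ccne2.L (2.102, SE 0.20) and the phosphatase gene cdc25b.L (1.63, SE 0.19). The mitotic kinase gene aurka.S was lower (-1.73, SE 0.34, edgeR adjusted p = 0.0456). The list's median was -0.12 and its mean 0.15, with an upward camera direction and an adjusted p of 0.762. Scaling by library size only gave a median of 0.14. Without Normal replicate 1 only 5 genes of the list were higher. Without EU-RNA replicate 1 or EU-RNA replicate 2, 14 or 21 were lower, and without either Normal library none was.

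Of 70 tested genes of DNA replication and its checkpoint, 2 were higher and 2 lower, the same as adjusted over the list alone. The sliding clamp gene pcna.L (2.07, SE 0.21) and the licensing factor gene cdt1.S (1.00, SE 0.20) were higher. The ribonucleotide reductase gene rrm2.1.L (-1.72, SE 0.27) and the origin recognition gene orc1.L (-1.07, SE 0.21) were lower. The calls of cdt1.S and orc1.L were lost without Normal replicate 1 (edgeR adjusted p = 0.431 and 0.240) and without Normal replicate 2 (0.0777 and 0.186), and that of rrm2.1.L without Normal replicate 1 (0.154). That of orc1.L was also lost with scaling by library size only (0.103). The list's median was -0.15 with a camera adjusted p of 0.267, and 0.10 with scaling by library size only. Without EU-RNA replicate 1 or EU-RNA replicate 2, 5 or 8 of its genes were higher and 13 or 16 lower.

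Of 126 features named for cytosolic ribosomal proteins, 1 was higher and 3 were lower by edgeR, 119 did not pass and the rest were below the filter. None passed when adjusted over the list alone, while 1 higher and 15 lower features had an unadjusted p below 0.05, DESeq2 called 1 and 8, and limma-voom 0 and 4. The lower genes included fau.S (-1.90, SE 0.35) and rps13.S (-1.18, SE 0.23), and both lost their calls without Normal replicate 1 (edgeR adjusted p = 0.431 and 0.173) and without Normal replicate 2 (0.0781 and 0.225). The higher gene was rps7.S, at 58.6 ± 23.7 CPM against 13.8 ± 3.21 CPM (SD, n = 2), a log2 fold change of 2.08 (SE 0.38, edgeR adjusted p = 0.0351), a call lost by limma-voom (limma adjusted p = 0.0588). Among tested genes matched to RefSeq, in the gene order of assembly Xenopus_laevis_v10.1, its neighbour was sox11.S, which was also higher (1.497, SE 0.22). Genes that were not tested may lie between them. The list's median was -0.22 and its camera adjusted p was 0.150, while scaling by library size only gave a median of 0.045 and no lower gene, with edgeR adjusted p of 0.0576 for fau.S and 0.0719 for rps13.S. Camera passed without EU-RNA replicate 1 (adjusted p = 0.0477, with 24 genes lower) and without Normal replicate 2 (adjusted p = 0.0294, with none lower). Without EU-RNA replicate 2, 10 genes were higher and 32 lower.

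Of 29 tested histone genes, 6 were higher and 1 was lower, with a median log2 fold change of 0.75, and adjusted over the list alone 9 were higher and 1 lower. hist2h2ab.L was at 239 ± 47.3 CPM against 30.9 ± 2.83 CPM (SD, n = 2), a log2 fold change of 2.95 (SE 0.23, edgeR adjusted p = 0.00388). hist1h1t.L (2.32, SE 0.24), hist1h2ad.1 (1.76, SE 0.19) and the H3.3 gene h3f3b.L (1.76, SE 0.21) were also higher, and the lower member was h1foo.L. The list's camera adjusted p was 3.46e-04. It had an adjusted p = 0.299 with an estimated correlation and 0.0769 by fry. Without EU-RNA replicate 2, 16 histone genes were higher and 5 lower, and without EU-RNA replicate 1, 4 were lower and the list's median was 0.38.

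In the list of RNA polymerase II, cap and spliceosome components, 10 of 89 tested genes were higher by edgeR and none lower, and 15 were higher and 1 lower adjusted over the list alone. The elongation kinase gene cdk9.L (2.38, SE 0.26), its cyclin gene ccnt2.L (2.17, SE 0.25) and the splicing factor genes srsf2.L (2.38, SE 0.19) and srsf3.S (1.61, SE 0.20) had the smallest p. The median of the list was 0.06, and its camera adjusted p of 0.0433 became an adjusted p = 0.174 with an estimated correlation. By fry the adjusted p was 0.0231. Camera did not pass without EU-RNA replicate 1, EU-RNA replicate 2 or Normal replicate 2 (adjusted p = 0.0753, 0.0998 and 0.193). Without EU-RNA replicate 1 or EU-RNA replicate 2, 20 or 24 of its genes were higher and 8 or 18 lower. Lower genes with an unadjusted p below 0.05 numbered 4, DESeq2 called 3 lower and limma-voom 1.

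Markers of late, differentiated cell types were mostly below the expression filter, with 21 of 69 features tested. Of these, 1 was higher, the insulin gene ins.L, at 22.4 ± 6.84 CPM against 1.89 ± 0.160 CPM (SD, n = 2), a log2 fold change of 3.57 (SE 0.56, edgeR adjusted p = 0.0209), a call lost by limma-voom (limma adjusted p = 0.0608). It was also the only call adjusted over the list alone. The muscle creatine kinase gene ckm.L (1.56, edgeR adjusted p = 0.130) and both homeologs of the myelin gene mbp did not pass. mbp.S had a log2 fold change of -1.67 (edgeR adjusted p = 0.160), and mbp.L had 0 and 2 counts in EU-RNA and 98 and 841 in total RNA (edgeR adjusted p = 0.131). Without EU-RNA replicate 1 the log2 fold changes were 1.32 for ckm.L, -2.68 for mbp.S and -7.76 for mbp.L. Without EU-RNA replicate 2 they were 1.67, -1.16 and -11.49. The list's median was 0.48 and its mean -0.39, with an upward camera direction and an adjusted p of 0.868. Without a filter the median was -1.58, and it was -0.61, -0.88 and -0.20 without EU-RNA replicate 1, EU-RNA replicate 2 and Normal replicate 1. Lower genes, of which edgeR called 0, numbered 4 at an unadjusted p below 0.05, 2 by DESeq2, 0 by limma-voom and 1 without a filter. In this list 3 genes were higher and 2 lower without EU-RNA replicate 1, and 5 and 3 without EU-RNA replicate 2.

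L and S homeologs of a gene were higher together more often than independent calls would give. Among 4523 pairs with both copies tested, both were higher in 136 pairs, the L copy alone in 157, the S copy alone in 126 and neither in 4104. If the calls of the 293 L and 262 S copies were independent, 16.97 pairs would have both. Shared reads between copies can add to the observed number. The L copy made up 55.5% of discordant pairs, a difference from the S copy that did not pass the test (exact two-sided McNemar test, p = 0.0743), and with no filter on low counts the share was 49.9%. Across pairs, which are not independent replicates, the log2 fold changes of L and S copies had a Spearman correlation of 0.27.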

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

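In this part, the thinned libraries were the only test chosen after the data were seen. The 7 lists of patterning, early zygotic, signalling and immediate early genes stayed above other genes by camera in every alternative with the preset correlation. This held with each library left out. With an estimated correlation the organizer (median 2.67) and signalling lists (1.51) lost their calls (adjusted p = 0.0900 for each). The rest of the 7 kept theirs only narrowly, at a shared camera adjusted p of 0.0498 against the threshold of 0.05. The untested list of mitochondrially encoded genes was not counted in this adjustment. DESeq2 called 2990 features higher and 1879 lower, a fit without a low-count filter called 2488 and 1134, and leaving out a library gave 1197 to 4577 higher and 151 to 5218 lower. The lower count was 142 with scaling by library size only, 387 with upper quartile factors, 385 with limma-voom and 680 with the replicate number as a block, and the cause was not tested. All 1246 higher and 236 lower features were shared with DESeq2 and with the unfiltered fit. Same-numbered libraries did not deviate together (correlation of deviations across features -0.023), so the block was not a pairing; it also gave 1789 higher features, and in that fit the list of polymerase and spliceosome components had a median of 0.027 and no call. Scaling by library size only moved the median log2 fold change of all tested features from 0.009 to 0.28. By this shift the medians changed sign for cell cycle regulators (0.14), ribosomal proteins (0.045), DNA replication (0.10), germ plasm (0.051) and maternal oocyte genes (0.17), none of which was called with that scaling. The call of the polymerase and spliceosome list held with some alternatives, such as library size only (median 0.32), and ended with the 10 most abundant features left out (median 0.024), a stricter filter (0.044), thinned libraries (0.067) and an estimated correlation (0.058). Its median turned negative with homeologs summed (-0.013), limma-voom (-0.010) and upper quartile factors (-0.019), and it ran from 0.029 to 0.12 with a library left out. With an estimated correlation and with fry the histone list (0.75) was not called. For late differentiation markers the median was -1.58 without a filter and -0.88 to 0.82 with a library left out. It was -0.28 to 0.12 for maternal oocyte genes and -0.32 to -0.054 for ribosomal proteins. The homeolog share moved to 49.9% without a filter. Depth was not the main limit: with all libraries thinned to 47598265 counts, edgeR called 1244 features higher and 241 lower.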

Other observations

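The tests of depth, of carry-over of all RNA and of a p53 response, and all values on name families and gene classes, were chosen after the results they bear on were seen. Among 318 families of genes that share a name stem and have at least 8 tested members, 9 held more genes higher in EU-RNA than the 781 of 16354 named genes would give (Fisher's exact test, Benjamini-Hochberg adjusted p below 0.05). The test takes homeologs and tandem copies as independent, although both homeologs were called in 136 pairs against 16.97 for independent calls, so these p-values are too small and the families are given as a description. Of these families, 7 have members in the fixed lists and are not separate from them: the ventx (9 of 10, adjusted p = 3.76e-09), nodal (9 of 11), sox (10 of 26, adjusted p = 1.63e-05), srsf (6 of 19, adjusted p = 0.0118), foxi (4 of 8), zic (4 of 9) and dusp genes (6 of 26, adjusted p = 0.0460). The other 2, with no member in those lists, were the frizzled genes, which encode Wnt receptors (7 of 17, adjusted p = 5.60e-04), and the lpar genes for lysophosphatidic acid receptors (4 of 11, adjusted p = 0.0460). No member of these 9 families was called lower by edgeR. The frizzled genes fzd7.L (2.24, SE 0.22), fzd7.S (2.80, SE 0.26), fzd8.L (2.61, SE 0.24) and fzd6.L (3.19, SE 0.39) and the receptor gene lpar6.L (2.98, SE 0.25) are examples, as log2 fold changes.

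Classes of genes by the RefSeq annotation differed in their medians. The 477 tested lncRNA genes had a median log2 fold change of 1.12, and 10000 random lists of the same size matched on mean expression had medians of -0.12 to 0.31 (central 95%). The 151 pseudogenes had a median of 1.26 (random lists -0.35 to 0.47) and the 41 tRNA genes a median of 2.45 (random lists -0.37 to 0.55). Copies within a class that share reads do not vary independently, so these ranges may be too narrow. The matching used mean expression over all libraries, EU-RNA included. The 17608 protein-coding genes had a median of -0.08. By single calls, 23 lncRNA genes, 9 pseudogenes, 3 tRNA genes and 850 protein-coding genes were higher, and these shares, which were not tested against each other, lay at 4.82%, 5.96%, 7.32% and 4.83% of each class.

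Features higher in EU-RNA were neighbours in the order of tested genes more often than shuffled calls were. In the RefSeq gene order, with untested genes left out, 107 adjacent pairs were both higher. Over 10000 shuffles within deciles of mean expression the mean was 46.4 and the maximum 74 (permutation p = 0.0001, the smallest these shuffles can give). Among pairs of genes with different name stems and symbols on both sides, 41 were both higher against a shuffled mean of 35.5 (permutation p = 0.193). The excess may therefore come from tandem families, such as the ventx, bix and nodal clusters, and from runs of symbol-less loci beside znf33a.L on chromosome 6L. Shared reads among tandem copies and joint transcription of a cluster were not separated by this test.

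Many features had reads in one EU-RNA library and none in the other. With at least 100 counts in one library and 0 in the other, they numbered 3115 in the EU-RNA pair and 1594 in the total RNA pair. After thinning all libraries to 47598265 counts they numbered 1938 and 120, a ratio of 0.0619, which argues against sequencing depth as the source. Their share was 18.5% in the lowest tercile of tested features by total RNA abundance and 0.102% in the highest tercile, a ratio of 182. Features at 0 in a library are bound to be rare whatever the source, so this ratio does not decide whether a small number of captured RNA molecules lies behind the losses, which stays open. No biological explanation was tested.

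The 79 tested members of the maternal lists had a median log2 fold change of -0.14. Of 1479 tested features of at least 100 CPM in total RNA, 10 lay far below carry-over of all RNA in proportion to total RNA. These 10 were called lower by more than 16-fold, among them LOC108705792 (-10.60, SE 0.75) and Xelaev18004208m (-8.63, SE 0.37). The test was chosen after the data were seen, and LOC108705792 alone would have met it, so it decides nothing about other RNA. The EU-RNA libraries came from other, injected embryos, so the levels of these 10 features before capture are not known. None of the 10 has a gene symbol. Named genes below 100 CPM in total RNA were also called lower by more than 16-fold, such as zfhx4.L (-4.75, SE 0.29) and parp2.L (-7.88, SE 0.76). They were picked for their low ratios, so they do not show how much messenger RNA of other genes was carried over. Carry-over of unlabelled maternal messenger RNA on the beads may still set the level of the maternal genes, and so may their continued transcription, and these cannot be told apart. The EU-RNA and total RNA levels of the maternal members correlated with a Spearman rho of 0.857 across genes, but rho was 0.885 for the 115 members of the dorsal, endodermal and mesodermal lists, so the correlation does not decide. A capture from embryos without EU was not analysed here.

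The raised list of immediate early, heat shock and p53 target genes may belong to the normal zygotic programme or to a response to injection or to EU. The 9 heat shock members had a median of 0.34, below the interquartile range of 1.19 to 3.15 of the other 52, so they did not carry the rise of the list. This median cannot exclude a heat shock response in the injected embryos. A gene's level in total RNA, maternal RNA included, also sets its ratio. A p53 response in the injected embryos stays open: p53 and its targets had a median of 2.80, and since total RNA of injected embryos was not analysed here, injection and capture cannot be told apart for these genes.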
